A study of Rattus norvegicus with 8 samples.

How the data were processed

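Total RNA from the hypothalamic paraventricular nucleus of 8 Sprague-Dawley rat pups, 4 males and 4 females at postnatal day 15, was labelled with Cy3 or Cy5 and hybridised to Agilent 2-colour arrays, per the labels' protocols. Each array held 1 sample per dye, and both samples of an array were of 1 sex, so 4 arrays carried the 8 samples. The series' design text calls the samples biological replicates. Within each sex, samples 1 and 2 shared array A and samples 3 and 4 shared array B; samples 1 and 3 were labelled with Cy3 and samples 2 and 4 with Cy5. Arrays A lay at slide position 4 and arrays B at slide position 3. The 2 male arrays came from 1 slide and the 2 female arrays from another, so slide and sex cannot be told apart in any comparison reported here.

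The deposited table gives log2 values, 1 column per sample and 1 row per array feature. Images were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes; background handling, filters and normalization are not given in the sources used here. The values themselves settled part of the scale. Within every sample, 2 to the power of the deposited log2 value was a whole multiple of 1 step for 100% of the values examined, with a tolerance of 0.01 of a step. The deposited log2 value is therefore the log2 of a spot intensity over 1 constant per sample, here called the reference intensity. It ranged from 1464 in female sample 3 to 3981 in male sample 2. Between 13932 and 13945 features per sample lay above 0, so the constant stood at nearly the same rank in each sample. The 1st percentile of a sample's intensity, over the 32033 features with a value in all 8 samples, is called its floor here. It is an estimate of the dim end and not a lower limit. The lowest intensities over all values were 32 to 100 in Cy3 and 54 to 76 in Cy5. The floor was 326 and 382 in Cy3 males, 244 and 248 in Cy3 females, 130 and 163 in Cy5 males and 74 and 76 in Cy5 females. Leaving out features missing in female Cy5 samples can raise the Cy5 floors of males.

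The table had 44254 rows, named by feature number alone. They are not paired with genes in the tables used here, so the planned tests of sex-linked genes, of gene lists, of markers of other cell types and of hypothalamic neuropeptides were not run, and the sex in the labels was not checked against sex-linked transcripts. Features are reported by number. Under the rule for naming, reduced for unnamed features, the 2 features with the smallest unadjusted p in each direction are named; any other named feature was chosen after its values were seen.

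Of the rows, 1377 had no value in any sample, 10844 had a value in some samples, and 32033 (72.4%) had a value in all 8. The comparison used the last of these. Missing values were most frequent in the female Cy5 samples, with 11125 and 11258 features missing, against 3519 and 4346 in the male Cy5 samples and 1388 to 1521 in the Cy3 samples. In all, 8797 features were missing in both female Cy5 samples and present in all Cy3 samples. These were dim, with a median log2 value of -2.49 in Cy3 against -0.36 for the features used. Leaving them out removes dim features because of values that differ between the sexes.

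Male and female samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 values as deposited, with dye as a fixed term and the array as a random block through duplicateCorrelation. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Differences are male minus female on the log2 scale. Spread within a sex was described as the percentage of features whose variance, after dye was removed within each sex, was larger in males. Its exact binomial 95% interval treats features as independent, which they are not. With dye removed, this variance holds only the difference between array A and array B in each dye. The fit was tested on simulated data with the real features' means, normal noise and 1 array correlation. These data held no effect of place and no sex difference tied to brightness. The shares called therefore need not hold for the real values, and a count of 0 there does not exclude large differences. With the array block the fit called 7.58% of 66 features simulated at a log2 difference of 0.585. It called 49.3% of 67 at 1, 98.5% of 67 at 2, and 9 of 31833 unchanged features. Among unchanged features 5.98% had an unadjusted p under 0.05, against 10.1% without the array block. No array was repeated on another slide, and the number of arrays limits the precision of every value.

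Same-numbered males and females share a dye and a slide position. The deviations of same-numbered samples from their sex's mean correlated across features at 0.696, 0.777, 0.855 and 0.731 for numbers 1 to 4. After dye was also removed within each sex the correlations were 0.150, 0.108, 0.150 and 0.108; removing dye leaves only 2 separate values. All were over 0.1, and the numbers were used as a block in further fits. The 2 values left without dye each compare array A with array B in 1 dye, with 1 pair of arrays per sex. They do not show that the numbers pair the samples. In the labels, dye and slide position are all that same-numbered samples share beyond what every sample shares. The labels tie no male to a female animal, and the source of the correlations was not tested. The fit with the replicate number as a block is given beside the count in the results.

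The design, the comparison and most alternatives were fixed before the data were examined. They were fits without the array block, without the dye term, with the replicate block, on array means, within 1 dye or 1 slide position, after median centring or quantile normalization, on the upper 75% or 50% of features by mean value, with a trended robust prior, with each sample or array left out, and with other thresholds. Alternatives chosen after seeing the data were the replicate block joined with the array block, with quantile normalization, with a local correction or on the upper 50% of features; subtraction of each sample's 1st percentile of intensity with 50 added; the 5th percentile of all values added on the linear scale before the log; the local correction alone or with quantile normalization; and features with at least 2 values in each sex. For the local correction, each value's deviation from its feature's mean was centred within 50 bins of brightness. The median of these deviations over neighbouring features, in a window of 11 lines and places, was then subtracted from each value. The grid has 532 lines of 85 features, read from the recurrence of empty rows. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.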

Results

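The series asked how male and female rat pups differ in gene expression in the paraventricular nucleus, a hypothalamic nucleus that holds oxytocin, vasopressin and corticotropin-releasing hormone neurons, in a model of infantile spasms with autistic behaviour. The dams had received 2 injections of betamethasone, a synthetic glucocorticoid, at 0.4 mg/kg on gestational day 15. The pups then received NMDA, an agonist of a class of glutamate receptors, on postnatal days 12, 13 and 15, and saline on days 13, 14 and 15. Every sample had this history, so sex was the only factor, and effects of betamethasone, NMDA or saline were not analysed here. Values are log2 intensities over each sample's reference intensity, for 4 males and 4 females.

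No feature differed between males and females at an adjusted p under 0.05 in the limma fit with the array as a random block, among 32033 features; the smallest adjusted p was 0.112. At an unadjusted p under 0.05 there were 7211 features (22.5%), of which 5361 (74.3%) were higher in males and 1850 higher in females. Of these, 1919 differed at least 1.5-fold, 1152 higher in males and 767 higher in females. This balance turned with the setting: 293 were higher in males and 714 higher in females after quantile normalization, 448 and 724 without the dye term, 248 and 712 on the upper 75% of features by mean value, 103 and 583 on the upper 50%, 820 and 834 after floor subtraction, 628 and 734 without male array B, 2136 and 2512 within slide position 3, and 287 and 760 with the 5th percentile added before the log. It moved further towards males in other settings, with 8249 and 862 when at least 2 values in each sex were enough, 2866 and 565 within Cy3, 2710 and 351 without female array B, and 1152 and 263 after the local correction. The correlation of samples within an array was 0.379. Of 36 other settings, 21 also gave 0 features. The 36 include other thresholds on the reported fit: an adjusted p under 0.1, with 0 features, and the 1919 at 1.5-fold. The rest used an adjusted p under 0.05. Among the 21 was the fit on array means, with a smallest adjusted p of 0.299. The outcome depended on how samples were blocked: limma called 2288 features without the array block and 3832 with the replicate number as a block, 3253 higher in males and 579 higher in females. Both of these fits take samples of 1 array as independent. The fit with the replicate block was not tested on the simulated data, so its rate of false calls is not known. Of the 3253, 1127 lay among the dimmest 10% of features. With the replicate block, limma called 1 feature after quantile normalization (35862, lower in males and named after its values were seen) and 1 among the brighter 50% of features (24930). Because each sex occupied its own slide, none of these counts separates sex from slide.

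None of the 2 features with the smallest unadjusted p in each direction passed the adjusted threshold. Feature 24930 was lower in males, at 0.53 ± 0.48 against 3.00 ± 0.29 in females (SD, n = 4 each), a log2 difference of -2.47 with an SE of 0.29. Feature 17452 was lower in males, at 0.19 ± 0.28 against 2.06 ± 0.42 (SD, n = 4 each), a difference of -1.87 with an SE of 0.20. Feature 16462 was higher in males, at 0.96 ± 0.16 against -0.06 ± 0.11 (SD, n = 4 each), a difference of 1.03 with an SE of 0.15. Feature 11565 was higher in males by 1.23 with an SE of 0.17, and it was dim, at -2.34 ± 0.73 against -3.57 ± 0.95 (SD, n = 4 each), with Cy5 samples below Cy3 samples in both sexes. Its female values lay at or near the floor of their samples, where the 1st percentiles were -2.92, -4.76, -2.58 and -4.61 for female samples 1 to 4, so the size of its difference is not settled; over the other settings it ran from 0.63, after the local correction with quantile normalization, to 1.80 after floor subtraction. The unadjusted limma p-values were 1.06e-05, 4.23e-06, 4.89e-05 and 3.67e-05 in this order, and each had an adjusted p of 0.112. Within the same dye, all male values lay on 1 side of all female values for each of the 4 features. The features were chosen for a small p in these same values, which favours such a separation, so it is no added support.

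**Figure D1:**
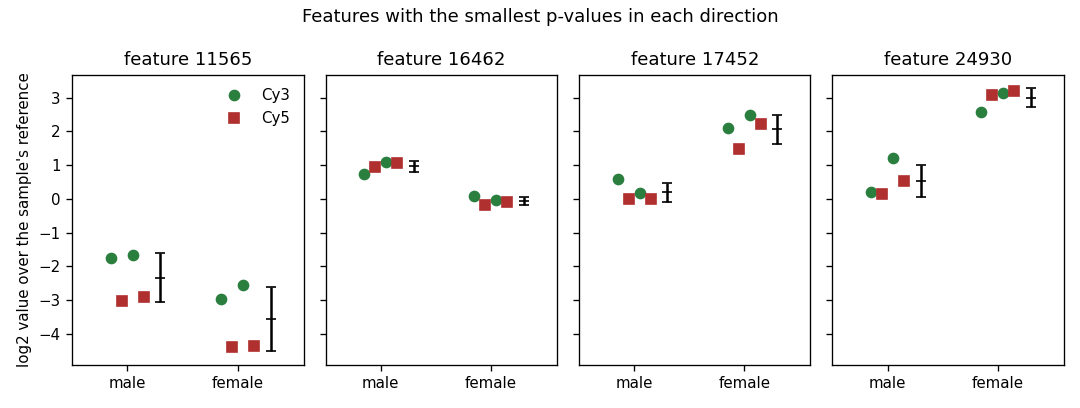
Log2 value over the sample's reference (vertical axis) of the 4 features with the smallest unadjusted p, for each male and female sample; circles are Cy3 and squares Cy5 samples, and bars give the mean and SD of 4 samples. Female values of feature 24930 average 3.00 and male values 0.53.

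Male and female values did not overlap at 2314 features (7.22%). A chance division of 8 independent samples into 2 groups of 4 gives 2.86%, but samples of 1 array are not independent and dye moves many features, so that share is no test of the excess. All 4 males were above all 4 females at 1384 features and below them at 930. Among the 32033 features with a value in all samples, none had every male at least 2-fold above every female, and 3 had every female at least 2-fold above every male: 24930 and, named after their values were seen, 13001 and 27189. Among the 8797 features left out for missing values in both female Cy5 samples, 9 had each male at least 2-fold above each female in Cy3. These features were dim, and selecting them for missing female values favours that direction. The 1076 features missing in both male Cy5 samples and present in all Cy3 samples were not examined in the same way. At feature 13001 the difference was -4.88, or 29.4-fold, with an SE of 0.74 and a limma adjusted p of 0.112. Its female values ran from 6.20 to 7.29, while the males of array A were at 0.92 and 0.33 and those of array B at 3.42 and 3.69. Feature 27189 had the same order, with males of array A at 3.30 and 2.91, males of array B at 5.56 and 5.93, and females from 6.93 to 7.86.

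In the values as deposited, the direction of the difference depended on the brightness of the feature. In the dimmest 10% of features the median male minus female difference was 0.41, and 1544 features were higher in males at an unadjusted p under 0.05 in the limma fit against 14 higher in females. The floor, taken as the 1st percentile of intensity over the features used, was higher in each male than in each female sample of the same dye. It was 382 and 326 in Cy3 males against 248 and 244 in Cy3 females, and 163 and 130 in Cy5 males against 76 and 74 in Cy5 females. On the log2 scale over the reference it was -2.32 and -2.24 against -2.92 and -2.58 in Cy3. In Cy5 it was -4.607 and -4.388 against -4.758 and -4.605, so male sample 2 was not above female sample 4. Leaving out features missing in female Cy5 samples can raise the Cy5 floors of males. In the brightest 10% the median was -0.12, with 89 higher in males and 400 higher in females. The change with brightness was steeper in the Cy3 samples, whose medians ran from 0.58 to -0.22, than in the Cy5 samples, whose medians ran from 0.24 to -0.01. This difference between dyes was not tested. Dim features were kept only with a value in both female Cy5 samples, which can lower the Cy5 difference at the dim end. Among the brighter 50% of features, 40.8% of those at an unadjusted p under 0.05 were higher in males, against 74.3% over all features. After quantile normalization the share over all features was 63.0%. The dimmest 10% then held 245 features higher in males and 115 higher in females at the same unadjusted p. The brightest 10% held 280 and 156. After floor subtraction these counts were 181 and 77 in the dimmest 10% and 123 and 174 in the brightest. After the local correction they were 1852 and 1, and 88 and 306. The direction in bright features therefore depended on the scaling. Quantile normalization also reduced a planted true shift, as described below.

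**Figure D2:**
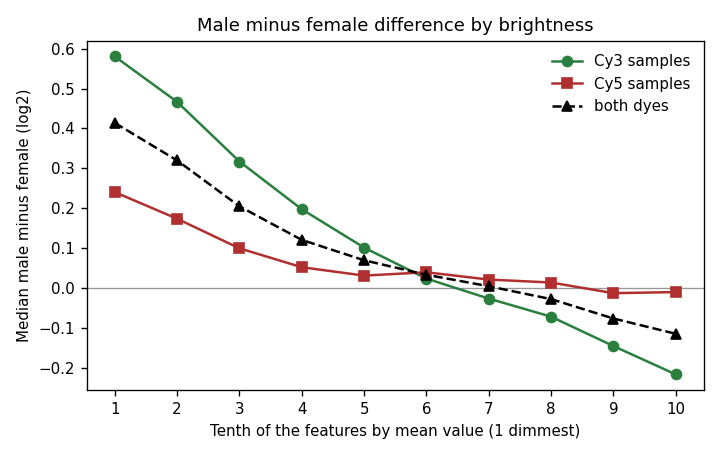
Median male minus female log2 difference (vertical axis) in 10 equal groups of the 32033 features by mean value (horizontal axis, dimmest first), for Cy3 samples, Cy5 samples and both. The line for both dyes runs from 0.41 in the dimmest group to -0.12 in the brightest.

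More features differed between dyes than between sexes in the same limma fit, with 18482 (57.7%) past an adjusted p of 0.05 between dyes, 13152 higher in Cy3 and 5330 higher in Cy5. Dye was compared within arrays and sex between arrays, so these counts differ in precision and do not compare sizes of effect. The SD of a sample's values was 1.81 to 2.13 in Cy3 and 2.54 to 2.63 in Cy5, a difference in scale over all features. Dye was balanced between the sexes. Within Cy3 samples limma gave 0 features at an adjusted p under 0.05 and 7693 at an unadjusted p under 0.05, and within Cy5 samples 0 and 3066. Within slide position 4 it gave 206 and 6970 features, and within slide position 3 it gave 7933 and 12238; these fits compare 1 male with 1 female array and carry no spread between arrays.

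The variance left after dye was removed was larger in males at 59.1% of features (exact binomial 95% interval 58.5 to 59.6%). The median SD was 0.17 in males and 0.15 in females. Each array held 1 sample per dye, so this variance holds only array A minus array B within each dye. It rests on 1 pair of arrays per sex and cannot tell spread among animals from a difference between arrays. The interval covers features and not arrays. The difference between the arrays of a sex was not tested between the sexes. Among the brighter 50% of the features, array A minus array B was at least 2-fold in the same direction in both dyes at 627 features in males and 36 in females. Of the 627, array A was the higher at 570. After the local correction the numbers were 139 in males, with array A higher at 114, and 28 in females. Across the brighter 50% of features the samples of male array A correlated with the female samples at 0.972 to 0.981 and with the samples of male array B at 0.953 to 0.963. The samples of male array B correlated with the female samples at 0.939 to 0.963.

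**Figure D3:**
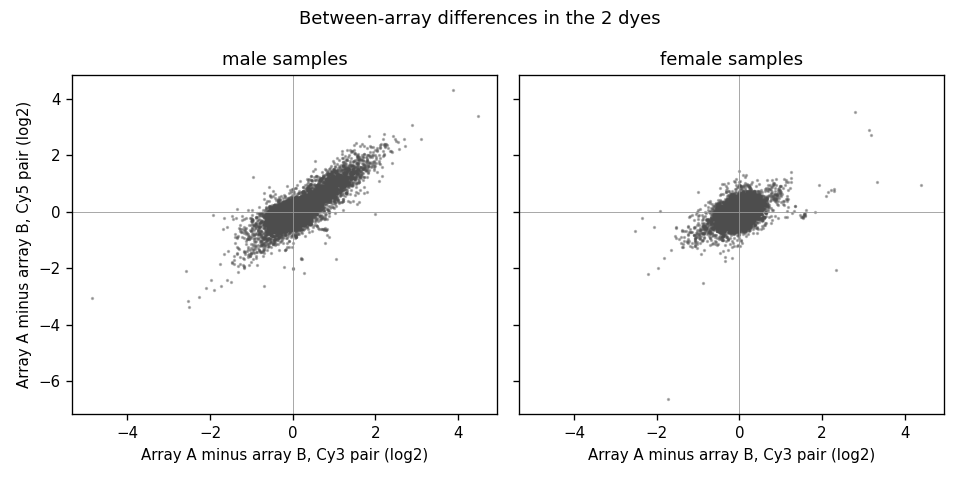
Array A minus array B (log2) for the Cy5 pair (vertical axis) against the Cy3 pair (horizontal axis), 1 point for each of the 16016 brighter features, in males and females. Differences were at least 2-fold in the same direction in both dyes at 627 features in males and 36 in females as deposited, and at 139 and 28 after the local correction, which is not drawn.

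The male minus female difference, centred within bins of brightness, also varied with the place of a feature on the array. The median over blocks of 28 lines ran from -0.17 in the last block to 0.10 in lines 57 to 84. Features 16462 and 17452 lie in lines 194 and 206, and the blocks that hold them had medians of -0.06 and -0.08. Blocks of 28 whole lines do not show effects of place over smaller areas.

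**Figure D4:**
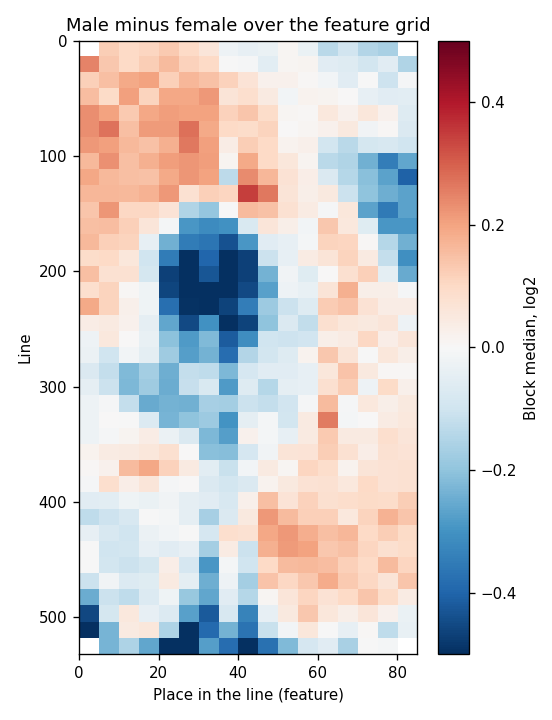
Male minus female log2 difference centred within brightness bins, as the median over blocks of 14 lines by 5 places (colour), over the line (vertical axis) and place in the line (horizontal axis) of the feature grid. Colours are limited to 0.5 in either direction, and medians over blocks of 28 whole lines ran from -0.17 to 0.10.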

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

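The 3 features below were examined because a single sample stood apart from the other 3 of its sex, by the gap to the nearest sample over the range. Among 24 such groups of 4 values, 3 stood apart. Chance gives about 1 in 20 for independent, unselected values. Most of the groups were features named for a small p or a large difference, and each group held both dyes and shared arrays. That rate therefore does not apply here. Feature 24930 in females had a ratio of 0.833, from 2.57 in female sample 1 against 3.08 to 3.19 in the others. Feature 13001 in females had 0.831, from 6.20 in female sample 2 against 7.11 to 7.29. Feature 27189 in females had 0.830, from 6.93 in female sample 2 against 7.71 to 7.86.

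Among features left out of the comparison for missing values, 20 exceeded the reference in at least 1 sample, and 11 of the 20 lay in the last 26 of the 532 lines of the grid. The brightest, feature 5236, singled out after its values were seen, stood at 5.86 and 2.46 in the 2 samples of male array A and at -2.07 to -4.76 in the other samples with a value.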

How the results depend on the processing

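Alternatives with the replicate block joined to another choice, the floor subtraction, the added 5th percentile, the local correction and the wider feature set were chosen after seeing the data. The count past the adjusted threshold, 0 in the reported fit, was obtained under 36 other settings, 27 chosen before and 9 after. It was 0 in 21. It was 2288 without the array block, 3832 with the replicate block, 4 without the dye term (16462, 24930, and 43043 and 44580, both lower in males; these and 30931 were named after their values were seen), 206 within slide position 4, 7933 within slide position 3 and 1 with the trended robust prior (17452). It was 3968 with the replicate block and the array block, where the correlation within an array was -0.011. It was 4727 with the replicate block and the local correction, and 1 with the replicate block after quantile normalization or on the upper 50% of features. Apart from the fit with both blocks, fits with the replicate block take samples of 1 array as independent. With samples or arrays left out the count ran from 0 to 7429. It was 7429 without male array A, 208 without male array B, 1 without female array B (30931) and 1 without male sample 3 (24930). Without an array, its sex gives no spread between arrays. The cause was not tested. The 36 include other thresholds on the reported fit. These gave 0 at an adjusted p under 0.1, and 1919 at an unadjusted p under 0.05 and 1.5-fold.

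The number at an unadjusted p under 0.05, 7211 in the reported fit, was 11323 with the replicate block, 11407 with the array block added, 10907 with the local correction added and 4568 with the replicate block on the upper 50% of features. It was 3066 within Cy5, 12238 within slide position 3, 4403 and 3018 on the upper 75% and 50% (fewer features tested), 4032 after floor subtraction, 4663 after the local correction with quantile normalization and 13637 with at least 2 values in each sex (41747 features). With samples or arrays left out it ran from 3318 without female array A to 12323 without male array A; it was 4597 without male sample 3 and 4593 without female sample 1. The percentage higher in males among these, 74.3, reversed to 40.8 on the upper 50% and 39.8 there with the replicate block. It was 56.9 without the dye term, 63.0 after quantile normalization, 60.3 with the replicate block as well, 56.1 on the upper 75%, 63.5 after floor subtraction, 55.1 after the local correction with quantile normalization and 88.7 with at least 2 values in each sex; left-out samples or arrays gave 61.7 to 87.6. The cause was not tested.

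The percentage of features with more variance in males, 59.1, was 62.6 after quantile normalization, 60.3 on the upper 50% and 55.2 after the local correction. With dye kept it was 71.7, and 58.4 to 70.5 when an array was left out as well. The 4 named features kept their direction in all 31 or 34 alternatives in which they had a value; 11565 passed the adjusted threshold in 8, 16462 in 8, 17452 in 9 and 24930 in 11. The replicate block, with samples of 1 array taken as independent, brought each of them to an adjusted p of 0.0276 in limma. Their adjusted p ran from 3.63e-06 to 0.517 over the alternatives. Fits of 1 gene per several probes and of gene lists were not run, because features carry no gene names here. The added 5th percentile, planned for linear values only, was run on intensities recovered from the log2 values. Dim features near the floor limit what these arrays show.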

Other observations

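Tests of place on the array and of its share in 1.5-fold differences, of place as the cause of the likeness within arrays, of a floor that differs between samples and of splits with the replicate block were chosen after the results were seen, as were the reading of the floor subtraction by dye, the planted shift, the divisions with the dye division set aside or with arrays whole, and several alternatives named in the processing. The sources of the differences below remain hypotheses, and sex itself stays open and untested for the differences between males and females, because sex and slide coincide.

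Features higher in males were concentrated at the dim end, with a median difference of 0.41 in the dimmest 10%. A floor that was not subtracted could give this. Subtraction brought the median to 0.17, which meets the bound of under 0.2 set beforehand, but the dyes then went opposite ways, 0.62 in Cy3 and -0.26 in Cy5, so this was not taken as deciding it. Quantile normalization brought it to 0.062, under the bound of 0.1 set beforehand for a brightness-dependent scale; a true shift of 0.41 planted in the values was also reduced, to 0.080, so that test was void and neither bound counts for an explanation. As an intensity, the floor over the features used was higher in every male than in every female sample of the same dye. Over the reference, which is the scale compared, that order held for every sample in Cy3 only. In Cy5 the floor was then -4.607 and -4.388 in males against -4.758 and -4.605 in females. The features left out for missing female Cy5 values can add to the Cy5 gap. A floor that differs between samples would raise nearly all dim features. In Cy3, 97.3% of the dimmest 10% were higher in males. So were 99.0% of the 8797 left-out features, though these were selected for missing female Cy5 values, which favours that direction. In Cy5 the share was 79.2% of the dimmest 10%, which fell between the bounds set. Keeping only features with a value in female Cy5 samples can lower that share. The explanations cannot be told apart for the dim features.

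The male minus female difference, centred within brightness bins, depended on the place on the array. Its rank correlation was 0.372 between adjacent features of a line and 0.389 between lines, against 0.004 and 0.017 for the mean level, and -0.033 for features farther apart in a line. Neighbouring features that carry unrelated probes could share such a difference through uneven hybridization, and the correlations meet what that explanation needs. After the local correction 7190 features had an unadjusted p under 0.05, a ratio of 0.997 to the number before. Features higher in males went from 5361 to 5788 and those higher in females from 1850 to 1402. The ratio cannot weigh place as the whole source of small p-values. The correction is centred within brightness bins, so it leaves any difference tied to brightness. It also lowered the median SD, from 0.173 to 0.155 in males and from 0.146 to 0.142 in females. Small p-values rose from 1558 to 1853 in the dimmest 10% of features and fell from 489 to 394 in the brightest. At 1.5-fold, features higher in females fell from 767 to 263, a ratio of 0.343, so place may account for many of these. Before and after, 1152 were higher in males, a ratio of 1. On the upper 50% of features by mean value, 103 were higher in males and 583 higher in females at 1.5-fold. Because the correction leaves differences tied to brightness, the 2 ratios do not show that place acts in 1 direction only. The correction moved feature 17452 from -1.87 to -1.40, and its unadjusted limma p from 4.23e-06 to 0.000615. Feature 16462 moved from 1.03 to 1.06, and its unadjusted limma p from 4.89e-05 to 1.71e-05.

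Samples of 1 array resembled each other. The difference between arrays correlated across features between the dyes at 0.726 in males and 0.447 in females. After the local correction it was 0.587 and 0.440, which argues against place as the whole cause, and after centring within brightness bins as well it was 0.576 and 0.424, which argues against a brightness-dependent shift. Litter, dissection, labelling and whatever the 2 dyes of an array share at a feature stay open and untested. The litter of each pup is not given in the sources used here. Cy5 males lay on the same arrays as Cy3 males, so the values that follow are no separate check of the choice. Features chosen in the Cy3 males as at least 2-fold higher on array A, after the local correction, numbered 285; in the Cy5 males 283 went the same way, 114 of them at least 2-fold, with a median of 0.89, and array A was at -0.005 and array B at -0.89 against the female mean. Those chosen as lower on array A numbered 71; 68 went the same way, 25 at least 2-fold, with a median of -0.76, and array A was at -0.84 and array B at 0.01 against the female mean.

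For chance, the 35 divisions of the 8 samples into groups of 4 were fitted with the same terms, except that Cy3 against Cy5 cannot hold a dye term and was fitted without it. The reported count past the adjusted threshold is 0, so all 35 of 35 divisions give at least as many whatever the data, and this comparison says nothing; the highest other gave 19249. At an unadjusted p under 0.05, 2 of the 35 reached the real 7211, the real one included, and the highest other had 20578. Without the array block 2 of the 35 reached the real 2288, and the highest other had 13755. The highest other was Cy3 against Cy5 each time, which measures the dye effect and points to the structure of the samples by dye. With it set aside, 1 of 34 divisions, the real one, reached each of the 2 counts, and the highest others were 6413 and 0. Most divisions break arrays apart, however, and only 3 keep them whole, too few for a share under 0.05; among those the highest others were 897 and 0. Chance is therefore not excluded. With the replicate block, 8 divisions part every same-numbered pair, again too few for a share under 0.05; the real one, 1 of the 8, gave 3832 features and the highest other gave 0. The others each move at least 1 pair between the sexes, so that both groups hold samples of both slides.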
